A study of Arabidopsis thaliana with 6 samples.

How the data were processed

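Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in 14-day-old Arabidopsis thaliana Col-0 seedlings that overexpress AtDEK3, a DEK-domain chromatin protein, fused to cyan fluorescent protein (CFP). Per the labels, an antibody against green fluorescent protein was used for the immunoprecipitation, and libraries were read as 36 bp single-end reads on a Genome Analyzer IIx with 1 lane per library. The series holds 6 samples, 3 ChIP libraries from 3 independent overexpressor lines (OE3-1, OE9-1 and OE17-4) and 3 inputs. Lines were numbered replicates 1 to 3 in that order, which is a name and not an order. The inputs were not analysed here, so no enrichment over input was computed.

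Each ChIP library came with 1 peak list, so peaks were called per line and not on pooled reads. Per the submitters' processing notes the genome build was TAIR 10. The aligner, the peak caller and the use made of the inputs are not given in the sources used here. Read counts per peak, in total and on each strand, are the authors' counts, deposited without normalization per the file headers. The false discovery rate (FDR) of each peak is the authors' value in percent, per the file headers. The normalized difference between strands is a fraction given by the authors, and it equalled the absolute difference of forward and reverse counts over all counts, within 0.006, in 100.0% of the OE3-1 peaks and in 100% of those of both other lists. The Wilcoxon filter p-value of each peak was also deposited by the authors, per the file headers. The deposited limits differed between the lists. The highest p-value was 0.1 in OE3-1 and OE9-1 and 8.9e-04 in OE17-4, or 9.99e-05 there without the rows written with 3 dots. Peak lengths in bp were deposited as end minus start in OE3-1 and as end minus start plus 1 in nearly all rows of the other lists. Start and end as deposited were used throughout. Empty rows and repeated regions were dropped, which removed 1, 2 and 2 repeated regions from OE3-1, OE9-1 and OE17-4. A set of 18 rows has its region written with 3 dots, unlike the rest of the rows, and these were kept in the main values and left out in an alternative.

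Sequencing depth of the libraries is unknown, since the lists hold reads inside peaks alone. Binomial intervals of shares are exact 95% (Clopper-Pearson) intervals and cover counting error only. No genome was used here. Gene names, types and spans came from the RefSeq gene table of assembly TAIR10.1, of which no coordinates are printed, with 27432 protein-coding genes on the 5 nuclear chromosomes. Names in the gene column of the lists matched this table for 99.5%, 98.3% and 99.1% of peaks in OE3-1, OE9-1 and OE17-4. Of the matched peaks, 98.9%, 94.6% and 98.4% overlapped their named gene or had no other gene wholly between. The share of midpoints in protein-coding genes was highest within 50 bp of no shift in OE3-1 and OE17-4 (90.3% and 74.3% at no shift, against 65.3% and 55.0% after a shift of -20000 bp), which was the check that spans and lists share positions. OE9-1 went the other way, with its lowest shares near no shift. They were 36.6% at -250 bp, 37.4% at no shift and 37.5% at 250 bp. At -500 bp and 500 bp they were 40.0% and 41.6%, and at -20000 bp 55.8%. The check by a highest share thus did not apply to OE9-1, but a low centred near no shift also ties its positions to the gene spans.

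The table gives no strand, exons or sequence. The planned classes of untranslated region, exon, intron and upstream sequence, the oriented profile along genes, the window of upstream sequence with the start of the gene, and the motif and GC comparison were therefore not run. Peak midpoints were classed, in this order, as in a protein-coding gene, a pseudogene or transposable element gene, a non-coding RNA gene, within 1 kb of a protein-coding gene on either side, or other intergenic. The gene span alone, set down beforehand as an alternative, took the place of the gene with its upstream sequence. Peaks carry no summit or fold, so midpoints were used and peaks were ranked by FDR within their own list. Strength was compared over regions shared by a pair of lines, since no position lay in a peak of all 3.

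Sets of peaks were compared by overlap of at least 1 bp. For regions of all 3 lines, overlapping peaks were merged and a merged region had to hold a peak of each line, so its outer peaks need not overlap each other. Chance was the mean of 1000 random placements of each list within its chromosomes with widths kept, and the p-values are permutation p-values, 2-sided, so 0.002 is the smallest possible. Overlaps had been planned as 1-sided tests, and the 2-sided form was used because a pair lay below chance. Gene-poor bins had been planned against a uniform share, and placement was used instead. Placement takes no account of where 36 bp reads can be mapped. A second placement, chosen after seeing the data, kept each peak inside or outside protein-coding genes. Gene-poor bins are the 20% of 100 kb bins with the fewest protein-coding genes, 239 of 1193. The gene lists, fixed before the data were examined, were DEK family, DEK3 partners, flowering time, circadian clock, heat stress, salt, drought and abscisic acid, histones, photosynthesis, housekeeping, developmental genes silent in seedlings, and ribosomal proteins by name in the table, some of them organellar. They were compared with 10000 random lists matched on gene length in 10 classes, with Benjamini-Hochberg adjustment over 11 lists. These are permutation p-values too. The partner list rests on what is known of the study. Genes for tRNA, snoRNA, snRNA and miRNA were compared with random placement. Correlations used 100000 permutations. Other p-values were adjusted by Benjamini-Hochberg within their family. A placement or gene-list p-value compares a library with random positions or genes and is not a test across lines. Genes and regions are not independent replicates.

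The methods were tested on simulated data of the real list sizes and 27432 genes. Unrelated simulated lists were called in 3.33% of pair comparisons and 6.67% of comparisons of genes hit in all 3 lists, and 20 of 20 planted shared regions were found. These lists were drawn by the same random placement that gave chance, and planted regions shared their midpoints. The rates therefore do not cover lists that favour or avoid genes, as the real ones do. For 30 of the longest genes, hit by length alone, matching in 10 length classes still gave a permutation p of 4.0e-04. Matching each member to the 200 genes nearest in length gave a permutation p of 0.262. That nearest-length match was added for this reason, after the data were seen, and is given beside the lists that passed.

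The rule for named genes, fixed before the data were examined, takes the DEK family, the 12 best-ranked regions shared by all 3 lines, up to 4 members of each list bound in all 3 lines, and the 2 members of each list bound in no line with the lowest identifiers. It yields few names, so genes were also named by their order among genes bound in all 3 lines, by read count or for a small count, after their values were seen. Alternatives set down beforehand were another overlap rule, the upper 50% of each list, equal list lengths, placement by gene-poor bins, flanks of 500 bp and 2 kb or taken first, bins of 200 kb, genes bound in at least 2 lines, unmatched random lists, and leaving out each line. Added alternatives were lists without the 18 rows, placement within class, genes with 1 kb on both sides, the authors' gene column, gene lists per line, the nearest-length match, also for pairs of lines with and without the 18 rows, and a common Wilcoxon limit. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.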

Results

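The series asks where in the Arabidopsis genome AtDEK3 binds. DEK3 is a chromatin protein with a DEK domain, encoded by AT4G26630. Binding was measured by ChIP-seq of DEK3-CFP in 3 independent overexpressor lines, grown on soil for 14 days under 16 h light and 8 h dark. Each line is 1 library, and the lines serve as the 3 replicates of the ChIP group. The 3 input libraries were not analysed here.

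The OE3-1 list held 5332 peaks with 1235876 reads in peaks, the OE9-1 list 3733 peaks with 814853 reads, and the OE17-4 list 3426 peaks with 549029 reads. Peaks were narrow. Their median length was 61 bp in OE3-1, 79 bp in OE9-1 and 137 bp in OE17-4, and they covered 361, 317 and 485 kb. The shortest had 20, 20 and 22 bp in the same order, less than a 36 bp read. Median normalized differences between strands were 0.11, 0.08 and 0.07. Forward and reverse counts were unequal in 40.6%, 25.7% and 10.2% of peaks (binomial test per peak, unadjusted p under 0.05). A median peak held 210, 202 and 136 reads in the same order. The strand values also depend on these read numbers, so they do not compare strand balance between the lists on equal terms. Total library depth is unknown, so read numbers are not compared between lines as binding.

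Where the peaks lay relative to genes differed between the lines. In OE3-1, 90.3% of 5332 peak midpoints fell in protein-coding genes (exact 95% interval 89.4 to 91.0%), and in OE17-4 74.3% of 3426 did (72.8 to 75.7%). In OE9-1 the share was 37.4% of 3733 (35.8 to 38.9%). Random placement gave 54.3%, 53.9% and 54.0% for OE3-1, OE17-4 and OE9-1, so the first pair lay above chance and OE9-1 below it (random placement, adjusted permutation p = 0.00272 for each line, from the smallest p the placements can give). Over lines the share was 67.3% ± 27.1 (SD, n = 3), and chance lay within that spread.

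OE9-1 peaks were instead above chance in the 1 kb beside genes, with 32.7% of midpoints against 19.1% by chance. In OE3-1 and OE17-4 these flanks held 5.23% and 6.60% of midpoints, against 19.0% by chance in both (adjusted permutation p = 0.00272 in each line). Intergenic sequence farther away held 26.4% of OE9-1 midpoints, against 1.65% in OE3-1 and 7.73% in OE17-4, with chance at 16.9%, 16.8% and 16.9%. More than 2 kb outside protein-coding genes OE9-1 was below chance, with 15.9% against 18.1% (adjusted permutation p = 0.00444). That class also holds pseudogenes and transposable element genes, where OE9-1 peaks were below chance, so it does not show where the intergenic excess ended. Pseudogenes and transposable element genes were below chance in OE3-1 (1.46% against 8.62%) and in OE9-1 (2.22% against 8.75%, adjusted permutation p = 0.00272 for both). In OE17-4 they held 9.78% against 8.82% by chance (adjusted permutation p = 0.0649). Placement took no account of where 36 bp reads can be mapped, so shares below chance need not mean avoidance. Non-coding RNA genes held 1.45% ± 0.132 (SD, n = 3) of midpoints against 1.30% by chance, and passed in no line. When the flank was given priority over overlapping genes, the OE3-1 flank share turned from below chance to 1.05 times chance.

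The lines also differed in position relative to gene ends. OE17-4 midpoints were most above chance 250 to 500 bp inside the nearer gene end, where 21.6% lay against 9.11% by chance. OE3-1 midpoints were most above chance deeper inside, where the 2 classes farthest from gene ends held 17.1% against 8.74% and 23.7% against 12.1%, both 1.95 times chance. OE9-1 midpoints were most above chance 500 to 1000 bp outside genes, with 13.9% against 7.17%, and inside genes they were above chance in the outermost 250 bp alone, at 1.22 times chance (random placement, adjusted permutation p = 0.00231 for each class named). Which end of the gene is the start is not known from the table used, so promoters and gene ends were not separated.

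**Figure D1:**
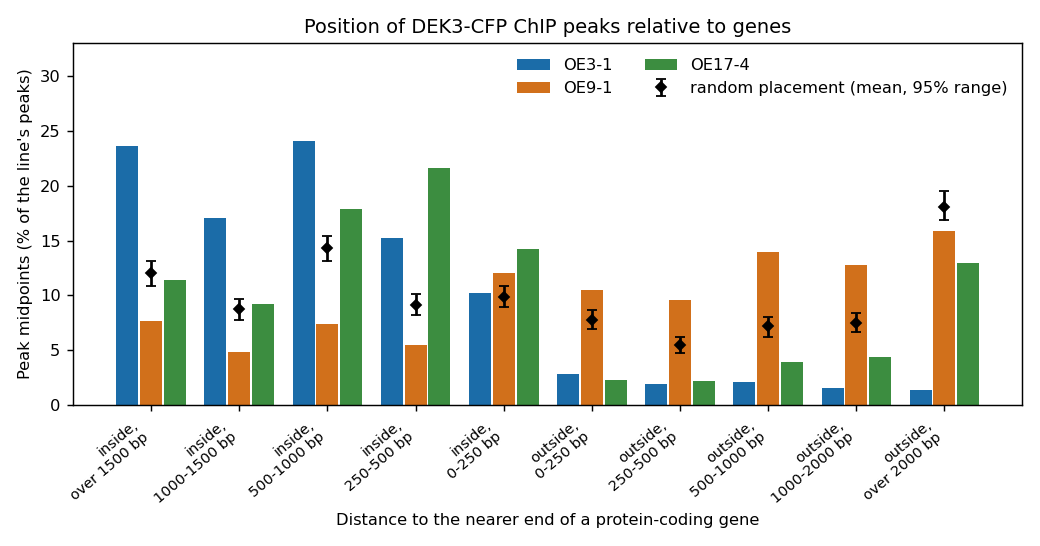
Percent of each line's peak midpoints (vertical axis) by distance in bp to the nearer end of a protein-coding gene (horizontal axis), with bars for OE3-1, OE9-1 and OE17-4 and diamonds for the mean over the lines of random placement. The error bars span the widest 95% range of the placements of any line. OE17-4 reaches 21.6% at 250 to 500 bp inside genes, and OE9-1 reaches 13.9% at 500 to 1000 bp outside genes.

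Gene-poor bins, the 20% of 100 kb bins with the fewest protein-coding genes, held fewer midpoints than chance in every line. OE3-1 had 4.03% of its midpoints there (exact 95% interval 3.52 to 4.60%), OE9-1 16.6% (15.4 to 17.8%) and OE17-4 17.8% (16.5 to 19.1%). Chance gave 19.8%, 20.1% and 20.2% (random placement, permutation p = 0.002 for each line, the smallest possible). The mean was 12.8% ± 7.62 (SD, n = 3), and chance lay within that spread, since OE3-1 was far below it and the other lines close to it. Placement took no account of where reads can be mapped, so avoidance of such bins is not shown.

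Few positions were shared between the lines. Of the OE3-1 peaks, 71 were overlapped by an OE17-4 peak, against 31.7 by chance (random placement, adjusted permutation p = 0.00599). OE3-1 and OE9-1 shared 32 peaks against 25.3 by chance (adjusted permutation p = 0.232). OE9-1 and OE17-4 shared 10 against 24.3, below chance (adjusted permutation p = 0.00599). The 71 peaks are 1.33% of the OE3-1 list and 2.07% of the OE17-4 list. A comparison chosen after seeing the data placed peaks inside or outside genes like the real ones. Chance was then higher for OE3-1 and OE17-4, at 40.1, and 21.2 for OE9-1 and OE17-4. Both still passed (adjusted permutation p = 0.00599 and 0.00999). The OE3-1 and OE9-1 overlap also passed, with 18.7 by chance (adjusted permutation p = 0.00999). This placement did not keep the distance of peaks to gene ends, in which the lines differed. It therefore cannot tell shared or avoided sites from those differences in position. Within the upper 50% of the lists by FDR, OE9-1 and OE17-4 shared 7 peaks against 6.41 by chance (permutation p = 0.913).

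A single merged region held a peak of all 3 lines, against 0.285 by chance (random placement, permutation p = 0.499). It was a chain, in which the OE3-1 peak overlapped both others and the OE9-1 and OE17-4 peaks did not overlap each other, so no position was shared by all 3 lines. On chromosome 4 the OE9-1 peak spanned 7128695 to 7128775, the OE3-1 peak 7128712 to 7128787 and the OE17-4 peak 7128786 to 7128946, with 232, 188 and 139 reads and FDRs of 4.57%, 1.12% and 0.02%. It lies between AT4G11845, the gene named in all 3 rows, and PLDGAMMA1 (AT4G11850), a phospholipase D gene, within 1 kb of both. Across shared regions no relation between the FDR ranks of a pair passed the test. Spearman's rho was 0.18 over 32 regions of OE3-1 and OE9-1 (Pearson's r 0.179), -0.08 over 71 of OE3-1 and OE17-4 (r -0.0295) and -0.21 over 10 of OE9-1 and OE17-4 (r -0.186), each with a permutation p adjusted over the 3 pairs of 0.566.

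Genes with a peak numbered 4301 in OE3-1, 1444 in OE9-1 and 2528 in OE17-4, and 7342 genes (26.8%) had one in any line. Genes with a peak of all 3 lines numbered 51, against 34.9 by chance (random placement, permutation p = 0.012). Placement inside or outside genes gave 49.9 by chance (permutation p = 0.921), so the number was not above chance once each line's share of peaks in genes was kept. The 51 genes had a median length of 5013 bp, against 2078 bp for all genes. Longer genes are hit more by chance. Placement within class gave medians of 2806, 2824 and 2827 bp for genes hit in OE3-1, OE9-1 and OE17-4 singly. No chance length was computed for genes hit in all 3. OE3-1 and OE17-4 had 523 such genes in common, against 261 by chance within chromosomes and 530 within class (permutation p = 0.731 for the latter).

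**Figure D2:**
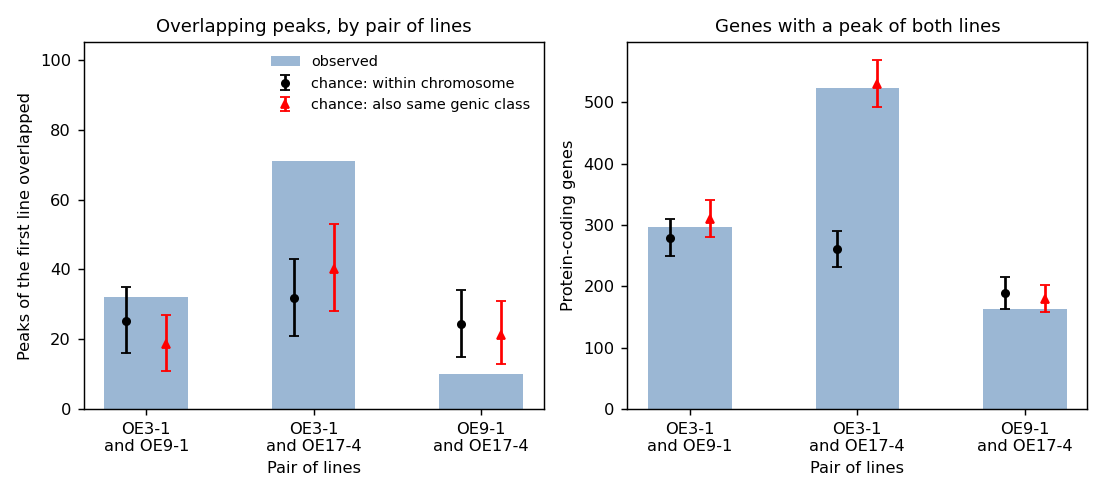
Left, number of peaks of the first line overlapped by a peak of the second, for each pair of lines. Right, number of protein-coding genes with a peak of both lines. Bars are observed numbers, and points with 95% ranges are random placements within chromosomes (circles) or also within the same class of sequence (triangles). OE3-1 and OE17-4 share 71 peaks, above both ranges, and 523 genes, within the range of placement by class.

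By FDR rank the genes of all 3 lines were led by AT1G27752. On chromosome 1 its OE3-1 peak at 9667096 to 9667196 overlapped its OE17-4 peak at 9667003 to 9667176. Its OE9-1 peak lay close by at 9667386 to 9667411, with a length of 26 bp and an authors' Wilcoxon filter p of 0.08. AT1G27752 was followed by DEK1 (AT1G55350), the calpain-type protease Defective Kernel 1. DEK1 had peaks in all 3 lines only when the 18 rows written with 3 dots were kept. Then came AT2G32170 and SRFR1 (AT4G37460), a negative regulator of immune responses. Next came AT4G30020, ATR1 (AT4G24520), a cytochrome P450 reductase, and the callose synthase gene GSL8 (AT2G36850). The chloroplast co-chaperonin CHL-CPN10 (AT2G44650), AT3G08670, THO2 (AT1G24706), which encodes a subunit of an mRNA export complex, NET1B (AT4G14760) and PPAN (AT5G61770) completed the first 12. In SRFR1 the OE3-1 peak at 17608776 to 17608818 and the OE17-4 peak at 17608682 to 17608762 on chromosome 4 lay near each other without overlap, and 3 OE9-1 peaks lay elsewhere in the gene.

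DEK3 itself carried peaks in all 3 lines. The lines overexpress DEK3-CFP and the inputs were not analysed, so reads of the transgene cannot be told from reads of the native gene. On chromosome 4 the OE3-1 peaks lay at 13431794 to 13431851 and 13435586 to 13435701, with 471 and 194 reads. The OE9-1 peak lay at 13435055 to 13435102 with 271 reads, and the OE17-4 peaks at 13430826 to 13430943 and 13430852 to 13430946 with 251 and 233 reads. All but the first of the OE17-4 peaks are among the 18 rows written with 3 dots, and without those rows DEK3 had a peak in OE17-4 alone. Among the other DEK-domain genes, AT5G63550 had a peak in OE9-1 and OE17-4, AT3G48710 in OE3-1, and AT5G55660 in no line. Of the 4 family members, 1 was bound in all 3 lines (adjusted permutation p = 0.28).

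Genes for DEK3 partners, topoisomerase 1 and the PDS5 family of cohesin cofactors, made up a list taken from what is known of the study, so it is not independent evidence. All 7 had an OE3-1 peak, against 2.57 by chance (random gene lists matched on length, adjusted permutation p = 0.0154, and 0.033 with the nearest-length match). TOP1ALPHA (AT5G55300) and the PDS5 gene AT5G47690 had peaks in all 3 lines, which is 2 of 7 against 0.0738 by chance (adjusted permutation p = 0.0682). Without the 18 rows, 6 of 7 had an OE3-1 peak (adjusted permutation p = 0.249) and none had peaks in all 3 lines. In the upper 50% of the OE3-1 list 5 of 7 did, against 1.48 by chance (adjusted permutation p = 0.125). Adjusted over all lists and all 5 ways of counting a gene as bound, the OE3-1 result had permutation p = 0.077.

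A list of seed, flower and meristem genes, drawn up as genes silent in seedlings, had OE17-4 peaks in 7 of 21 members against 1.99 by chance (random gene lists matched on length, adjusted permutation p = 0.0352). They were the seed storage protein genes CRU2, CRU3, CRA1 and SESA2, the embryo regulator LEC2, PHE1 and the meristem gene KNAT2. FUS3 had an OE3-1 peak, STM and KNAT1 had OE9-1 peaks, and LEC1 and SEP3 had none. No member was bound in at least 2 lines. Expression was not measured here, and the meristem genes KNAT2, KNAT1 and STM are active in the seedling shoot apex. The OE17-4 result had adjusted permutation p = 0.0726 with the nearest-length match (7 against 2.09) and 0.13 with 1 kb on both sides of genes (8 against 2.96). It had 0.235 in the upper 50% of the list (4 against 1.02) and 0.088 over all lists and ways of counting.

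No list passed for genes bound in all 3 lines (permutation test by random gene lists, 0 of 11 lists, with 1 at an unadjusted p under 0.05) or in at least 2 lines (0 of 11, with 0 unadjusted). Lists with 0 genes bound in all 3 lines had 0.0065 to 0.14 by chance. Fewer than chance could not have been called for them. In OE9-1 no list passed (0, with 0 unadjusted). For OE9-1 and OE17-4 together, leaving out OE3-1, the DEK family passed with 2 of 4 genes, DEK3 and AT5G63550, against 0.0606 by chance (adjusted permutation p = 0.0286, and 0.0176 with the nearest-length match). The OE9-1 peak of DEK3 is 1 of the 18 rows, and without them AT5G63550 alone was left and the list did not pass (unadjusted permutation p = 0.112). Peaks in DEK3 may also hold reads of the transgene. For the other pairs 1 of 4 was bound, against 0.212 without OE9-1 and 0.136 without OE17-4 (adjusted permutation p = 1 for both), and these p-values are adjusted over the lists and not over the pairs. Among 24 flowering genes 9 had a peak in a single line, including FLC in OE9-1, FCA and CO in OE3-1 and FVE in OE17-4, while GI and FT had none. Per line, 5 had an OE3-1 peak against 6.92 by chance, 3 an OE9-1 peak against 2.21 and 1 an OE17-4 peak against 3.23. The clock gene ZTL had peaks in OE3-1 and OE9-1, TOC1 in OE17-4, and LHY in none. Of 23 heat stress genes 6 had a peak in a single line, among them HSFA2 and HSP101 in OE3-1, and HSP70 and MBF1C had none. OE3-1 peaks lay in 4 against 3.36 by chance, OE17-4 peaks in 2 against 2.04 and OE9-1 peaks in 0 against 1.10. Of 30 salt, drought and abscisic acid genes 5 had an OE3-1 peak, 6 an OE17-4 peak and 0 an OE9-1 peak, and the list passed in no line. Chance was 6.34, 3.27 and 1.97 in that order. HAB1 had peaks in OE3-1 and OE17-4, HAB2, ABF2, ABF4 and HKT1 in OE3-1, SOS1, COR15A, LTI65, ABI4 and RD22 in OE17-4, and COR47 and ERD10 in none. Of 39 histone genes 6 had a peak in a single line, with HTB1 and AT1G07660 in no line. OE3-1 peaks lay in 4 against 2.08 by chance, OE17-4 peaks in 2 against 2.21 and OE9-1 peaks in 0 against 1.08. Of 29 photosynthesis genes 2 had a peak, LHB1B2 and RCA, both in OE17-4, and LHCB6 and DRT112 in no line. Chance was 2.16 in OE17-4, 2.81 in OE3-1 and 1.03 in OE9-1. The flowering, heat stress, histone and photosynthesis lists passed in no line. In the housekeeping list, ACT8 had peaks in OE3-1 and OE17-4, and AT1G07920 and AT1G07930 had none. Ribosomal protein genes had OE3-1 peaks in 10 of 50 cases against 5.00 by chance (adjusted permutation p = 0.265), and RPS15 and RPS15A had none in any line.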

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

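Alternatives chosen after the data were seen were placement within class, lists without the 18 rows written with 3 dots, genes with 1 kb on both sides, the authors' gene column, the common Wilcoxon limit, gene lists per line, and the nearest-length match, also for pairs of lines. Of 153 values under an alternative, 122 kept their direction and side of the threshold or moved little, 12 lost and 4 gained a call, 5 moved and 10 turned. Not all of the 122 could have changed. Flanks of 500 bp and 2 kb leave the shares in protein-coding genes as they are, since genes are classed first. Means without a line were held against the SD of the 3 lines, which leaving out a line cannot exceed. Some of the 10 that turned are counts of 0 against 0.0154 to 0.071 by chance, where no direction could be told. The ratio of 0.413 without OE3-1 is among the 10 for both regions and pairs, as the same overlap. Shares in protein-coding genes kept their direction and side for each line under every other alternative run, as did gene-poor bins. Over the midpoints in genes the mean without a line ranged from 55.8% to 82.3%. Values below are ratios to chance, and the causes of changes were not tested. The 51 genes of all 3 lines, at 1.46, fell short of the threshold in the upper 50% of lists (1.75, permutation p = 0.154), under placement within class (1.02, permutation p = 0.921), without the 18 rows (1.32, permutation p = 0.0799), with 1 kb on both sides (1.12, permutation p = 0.256) and by the authors' gene column (1.12, permutation p = 0.332). Leaving out each line gave 0.858 to 2.01, the lowest without OE3-1, below chance, and 1.07 without OE17-4 did not pass (permutation p = 0.25). The overlap of all pairs together, at 1.39, ranged from 0.413 without OE3-1 to 2.25 without OE9-1, and 1.27 without OE17-4 did not pass (permutation p = 0.218). For regions shared by all lines used, leaving out each line gave 0.413 to 2.25, and none was left with overlap over 50% of the shorter peak (0) or in the upper 50% of lists (0). OE3-1 and OE9-1 turned to 0.857 with midpoints within 250 bp (permutation p = 0.208) and passed under placement within class (1.71, permutation p = 0.00799). OE9-1 and OE17-4 turned to 1.09 in the upper 50% of lists. With the flank taken first, the OE3-1 flank ratio turned to 1.05 and the mean flank share moved to 39.8%. Gene lists that passed numbered 1 with unmatched random lists (the DEK3 partners), 1 in OE3-1 alone, 1 in OE17-4 alone and 0 to 1 when each line was left out. The partner genes bound in all 3 lines fell to 0 in the upper 50% of lists and to 0 without the 18 rows. Partner genes with an OE3-1 peak did not pass in the upper 50% of the list (3.39, adjusted permutation p = 0.125) or without the 18 rows (2.34). In OE17-4 the developmental list did not pass in the upper 50% of the list (3.92), with 1 kb on both sides (2.70, adjusted permutation p = 0.13) or with the nearest-length match (3.35). The alternatives that need exons, strand, summits or sequence were not run. No paired analysis was possible because the inputs, which share replicate numbers with the ChIP libraries, were not analysed here. Unknown library depth keeps sites missed in a line from being told from sites not bound.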

Other observations

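The tests of a coordinate offset, of displaced coordinates and of repeat copies, with its Fisher tests, were chosen after the result was seen, and the other tests before. The offset test replaced an earlier one whose bound had not been met because a shift of -50 bp borders no shift, and the displacement test replaced one that rested on the gene column. The peaks with the most reads were singled out after their values were seen. In OE3-1 the highest, with 21288 reads, lay in pseudogene sequence on chromosome 3 at 13538215 to 13538355. In OE9-1 it was intergenic on chromosome 5 at 11709106 to 11709157 with 8349 reads, and an OE17-4 peak at 11709111 to 11709260 with 12312 reads overlapped it. The OE17-4 maximum, 15690 reads, lay at 3253167 to 3253188 on chromosome 5, in AT5G10340. NRPC2 (AT5G45140), a subunit gene of RNA polymerase III, held 5 OE3-1 peaks, the most of any gene in that list, and none of the other lines. Genes for tRNA, snoRNA, snRNA and miRNA passed in no line (permutation test by random placement, smallest adjusted p = 0.575).

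Overlap of the 3 lines at few positions was weighed against calls near the authors' threshold. Overlap over chance between the upper 25% of the lists by FDR was 1.27 times that between whole lists, with Poisson limits of 0.61 to 2.34. These limits hold both bounds set for this explanation, so it stays open. A constant offset between lists would bring most peaks into overlap at some shift, but the highest number at any shift of up to 5 kb was 73 for OE3-1 and OE17-4, 2.13% of the shorter list, 35 for OE3-1 and OE9-1 and 39 for OE9-1 and OE17-4, which argues against it. No biological explanation was tested, and the lines being independent insertions stays open.

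Of the explanations for OE9-1 peaks lying outside protein-coding genes, 3 were argued against. Under the Wilcoxon limit of the OE17-4 list, 34.6% of 471 OE9-1 peaks lay in genes (exact 95% interval 30.3 to 39.1%), against 74.3% in OE17-4. A constant displacement of the OE9-1 list is argued against up to 5 kb, since no such shift brought more than 55.3% of its midpoints into genes (exact 95% interval 53.7 to 56.9%), against 74.5% at the best shift of OE17-4, -50 bp. More OE9-1 peaks in gene-poor bins were not seen to begin with, at 16.6% against 20.1% by chance and 17.8% in OE17-4. Outside gene-poor bins 42.5% of OE9-1 midpoints lay in genes (40.8 to 44.3%), against 63.7% by chance there. Whether the line, the library or the use of its input set this share was not tested, and the design gives no group to test it with.

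Reads of several repeat copies, collected in gene-poor bins, would place most of the peaks with the most reads there. Over the 3 lists, 18.1% of the 127 peaks in the top 1% by reads lay in such bins (exact 95% interval 11.8 to 25.9%). That argues against gene-poor bins as the place of most of these peaks, but repeat copies outside such bins were not tested. The pooled share also rests on lists that differed, with 3 of 54 in OE3-1 (5.56%) and 7 of 38 in OE9-1 (18.4%). The top 1% reaches down to 473, 523 and 389 reads in OE3-1, OE9-1 and OE17-4. Of the 5 peaks with the most reads in each list, 10 of 15 lay in such bins (66.7%, exact 95% interval 38.4 to 88.2%), so for these it stays open. In OE17-4 13 of the 35 peaks in its top 1% did, 37.1% against 17.6% of its other peaks (Fisher's exact test, adjusted p = 0.018), so for that list it stays open too.

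The 18 rows written with 3 dots lay in 8 genes, DEK3, TOP1ALPHA, AT5G47690, EFS, CMT3, MBD9, HB-1 and DEK1, and included 2 FDRs over 5%, the highest at 8.93%, and 2 rows with no Wilcoxon p-value. In OE17-4 such a row at DEK3 overlapped another row of the same list, with FDRs of 0.026% and 1.17%. Of the 51 genes bound in all 3 lines, 5 rested on these rows. When a peak lay outside the gene its row names, that gene was at lower coordinates in 99.6% of 1133 cases in OE3-1, 99.8% of 2379 in OE9-1 and 99.3% of 851 in OE17-4. Another gene lay under the peak in 809, 307 and 420 of these. The share of OE9-1 peaks inside the gene their row names was 35.2% at no shift, 43.2% at a shift of -500 bp and 50.7% at -1000 bp, towards the lower coordinates at which the named gene lies. For OE17-4 it was 74.9% at no shift and 61.8% at -1000 bp, and for OE3-1 78.6% at no shift, 80.3% at -500 bp and 75.4% at -1000 bp. Since the column names the gene at lower coordinates, these shares do not decide whether the OE9-1 list is displaced.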
